A study of Rattus norvegicus with 24 samples.

How the data were processed

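The data came from GeoMx digital spatial profiling of skin wounds in diabetic rats. Per the labels' protocols, male Sprague-Dawley rats were made diabetic with streptozotocin at 5 weeks of age, received splinted full-thickness skin defects of 8 mm, and had the wounds taken at day 7. Fixed, paraffin-embedded sections were hybridised with indexed RNA probes, regions were chosen, and each area within a region was defined by positive immunofluorescence before its probe tags were released by light and sequenced. The labels do not name the fluorescent markers, do not say what distinguishes Segment 1 from Segment 2, and do not spell out the short region name "mac". There were 24 areas: 3 treatments (Sham, Gel, CuNZ@Gel), 2 numbered specimens per treatment, 2 regions per specimen and 2 segments per region. The labels do not say that a numbered specimen is an animal. The p-values rest on these specimens alone, with a spread largely pooled over targets, and may be too small.

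Each deposited file gives a signal value for 19963 targets, of which 1 is a negative probe. The counting software, the probe filtering and the scaling step are not given in the sources used here. The values themselves had a 75th percentile of 12.3 in the median area (lowest 12.1), as scaling to the 75th percentile would give. In every area between 99.98% and 99.995% of values were whole multiples, within 0.01 of a count, of the lowest value, so whole counts could be recovered. Recovered totals ran from 86385 to 1476500 per area (median 340370). No target was listed at 0, and the lowest value equalled 1 count, which sets a floor that lies higher in shallow areas. Target symbols were used as the files give them. They follow mouse naming, and 16665 of them equal a symbol of the rat annotation GRCr8 (17113 with synonyms and any case). Probe sequences were not used here, so a probe that reads rat RNA poorly cannot be recognised except by its low value.

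The deposited values were analysed as log2(value + 1), so fold changes are on that scale and understate changes of low targets. Targets above the negative probe in at least 4 areas were kept (19728). For the treatment comparisons the log2 values of the 4 areas of a specimen were averaged and all 6 specimens were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust). For the segments the 2 areas of a specimen and segment were averaged and the specimen was a block. The treatment by segment interaction was an F test in that fit. Adjusted p-values are Benjamini-Hochberg over all targets tested, with a threshold of 0.05. The plan foresaw a count test if the files held counts. They held scaled values, so the test planned for scaled values was used, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered counts, summed per specimen, were added after the data were seen. They called 369 and 152 targets between Gel and Sham, 165 and 59 between CuNZ@Gel and Sham, and 138 and 55 between CuNZ@Gel and Gel. limma's spread for a typical target rested on 133 prior degrees of freedom against 3 of its own, so the very small p-values reflect a spread pooled over targets. The SD used was 0.213 for Tagln, 0.186 for Mt2 and 0.198 for C3, against 0.388, 0.364 and 0.373 of their own. The SEs given below rest on the SD used. Acta2 nearly kept its own (0.919 against 0.976), and for H2-Ab1 the SD used was the larger (0.233 against 0.205).

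A background was taken in each area as the 99th percentile of 1116 odorant and pheromone receptor targets (11.4 to 21.6, median 14.3). In this text a target is above background when it exceeds that value in at least 4 areas, which held for 5554 targets. The 34 gene lists (623 genes) were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The comparisons, the tests, the lists and the rule for named genes were fixed before the data were examined. Named genes were, per comparison, the 8 largest rises and 8 largest falls among targets past the threshold that moved the same way in every pair of specimens, up to 4 members of each list with the smallest p, and 19 genes given in every treatment comparison whatever their values. Not every gene the rule takes is reported here. Alternatives covered the scaling, the filter, the pseudocount, the averaging, the test, the unit of analysis, the specimen number as a block and the omission of each specimen. No area fell under the planned limit of depth, so that omission was not run.

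The fits were tested on simulated areas with the real depths and with 100 targets changed by 1 and 100 by 2 log2 units, all above background. Every target was given the same typical spread, a log2 SD of 0.369 between regions and 0.0611 between specimens. Real targets differ in spread: the SD of specimen means was 0.205 for H2-Ab1 and 0.976 for Acta2. The shares recovered therefore need not hold for them. Over 19890 targets, the Gel against Sham fit recovered 58% of targets changed by 1 log2 unit and 98% of those changed by 2, with 9 of 165 calls on unchanged targets, 0 of them above background. In Segment 2 alone the shares were 13% and 76%. The segment fit, over 19880 targets, recovered 88% and 100%. The interaction test recovered 3% and 62%, and 6 of its 71 calls were on unchanged targets, 5 of them above background. With a simulated shift of 1 log2 unit in 1 of 34 lists between Gel and Sham, camera called that list at the preset correlation and called 0 lists with an estimated one. The simulated members varied independently, while the estimated correlation of the real lists reached 0.289 between treatments over both segments and 0.430 between segments, so the simulation does not tell which of the tests is right for them.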

Results

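GeoMx areas of day 7 wounds from 3 treatments of diabetic rats were compared: Sham, a hydrogel (Gel), and the same kind of gel carrying a nanozyme (CuNZ@Gel; the labels give no composition). The series title presents the gel as acting on inflammation through epigenetic change. Each treatment had 8 areas from 2 specimens, and values below are means of specimens in Q3-scaled signal with their SD (n = 2). Depth differed between the segments. Segment 1 areas held 322151 to 1476500 counts (median 533134), Segment 2 areas 86385 to 688507 (median 170040), and Segment 2 was the shallower in 11 of 12 regions. A median of 28.5% of targets stood at 1 count in Segment 2 areas and 2.19% in Segment 1 areas.

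**Figure D1:**
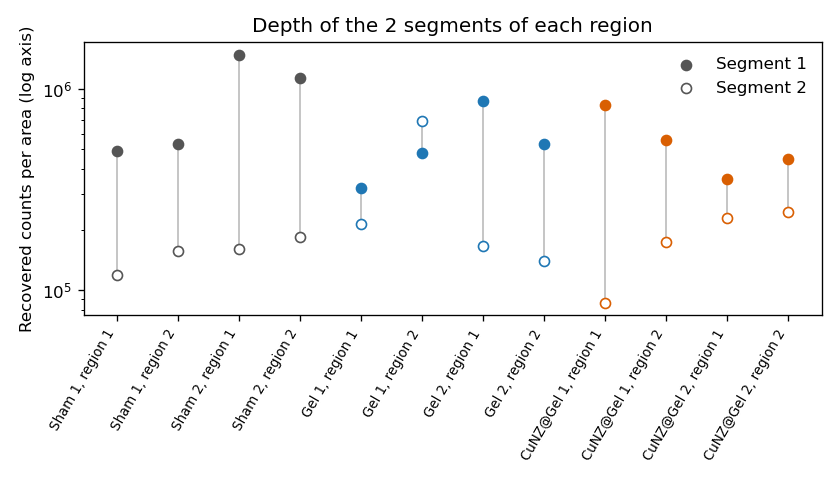
Recovered counts per area (log axis) for the 12 regions, with Segment 1 as filled and Segment 2 as open circles joined by a line. Segment 2 lies below Segment 1 in 11 of the 12 regions.

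Gel against Sham asks what the gel without nanozyme did to the wound. Mt2 and Mt1, which encode metallothioneins, small metal-binding proteins, were far higher in Gel: Mt2 stood at 114 ± 34.0 in Sham and 2918 ± 869.8 in Gel, a log2 change of 4.67 (SE 0.19, adjusted p = 1.6e-37), and Mt1 rose by 2.82 (SE 0.19). The Mt2 call was lost under quantile normalization (adjusted p = 0.0805), where the log2 change was 5.24. The complement genes C3 (16.4 ± 7.06 to 173 ± 41.6, log2 change 3.27) and Cfb (1.94) rose, as did Prg4, which encodes the lubricant protein lubricin (2.84), Zbtb16 (2.15), Lhx8 (2.04) and Gja5 (1.99). Tagln, a gene of contractile cells, and the collagen gene Col12a1 fell: Tagln went from 74.7 ± 8.49 to 8.71 ± 4.26 (log2 change -3.01, SE 0.21, adjusted p = 9.6e-24), and Col12a1 from 1682 ± 62.8 to 248 ± 55.5 (-3.02).

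Of 14 measured myofibroblast and contractile genes, 3 fell (Tagln, Tpm1 by -2.23 and Cald1 by -1.26) and 0 rose, or 5 fell adjusted over the list alone. The median of the 7 above background was -2.23. The list was called lower (adjusted p = 6.7e-23), but not with an estimated correlation (adjusted p = 0.0920 with an estimated correlation). Acta2, the smooth muscle actin gene, named after its values were seen, had a log2 change of -3.43 (SE 0.92) and was not past the threshold (adjusted p = 0.316). Its Gel specimens lay at 4.54 and 6.88 on the log2 scale. Of 21 collagen and matrix genes, 7 fell and 0 rose (10 and 1 adjusted over the list alone), among them Col12a1, Thbs2 (-2.96), Plod2 (-1.74) and the fibronectin gene Fn1 (-1.56), with adjusted p = 2.7e-19 for the list and 0.102 as the adjusted p with an estimated correlation. Of 18 fibroblast genes, 3 fell and 0 rose (4 and 0 adjusted over the list alone): Fap (-1.32), Mfap5 (-1.48) and Lum (-1.13), with adjusted p = 1.9e-11, and adjusted p = 0.265 with an estimated correlation. Col1a1 (390 ± 132 in Sham, 111 ± 57.4 in Gel, adjusted p = 0.259) and Col3a1 (12272 ± 2891 and 4754 ± 3104, adjusted p = 0.479) did not pass. Of 14 adipocyte genes 0 passed, also adjusted over the list alone. The list was called higher in Gel (adjusted p = 0.0259, and adjusted p = 0.449 with an estimated correlation), with a median of 1.16 over the 2 genes above background. The proteases Mmp2 (-1.04) and Mmp14 (-1.02) fell, each lost under 3 alternatives, and the list of proteases and inhibitors was not called (adjusted p = 0.0504). Of 19 wound growth factors Wnt5a (-1.40) and Tgfb2 (-1.07) fell and Fgf10 (1.13) rose, also adjusted over the list alone (list lower, adjusted p = 0.00495, and adjusted p = 0.265 with an estimated correlation). The Tgfb2 and Fgf10 calls were lost under 6 and 5 of 22 alternatives, among them DESeq2 and leaving out Gel specimen 1.

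Other large falls were H2-Ab1, an MHC class II chain, from 195 ± 30.3 to 4.41 ± 0.44 (-5.25, adjusted p = 1.7e-43), C1qtnf3 (-4.78), Ms4a4a (-3.91), Ccn3 (-3.77), Itga11 (-3.58), Mdk (-3.25), Mfap2 (-3.12) and the haemoglobin gene Hba-a1 (-5.15). H2-Ab1 was above background in 8 of 8 Sham areas and in 0 of 8 Gel and 0 of 8 CuNZ@Gel areas, while Cd74 (0.42, adjusted p = 0.876) and the class II gene H2-Eb1 (0.30, adjusted p = 0.925) were above background in every area. Of 20 endothelial genes 1 rose, Apln (0.95), or 4 adjusted over the list alone (list adjusted p = 0.0103, and adjusted p = 0.369 with an estimated correlation). The Apln call was lost under 7 of 23 alternatives, including leaving out Sham specimen 2 or Gel specimen 1. Of 20 pan-macrophage genes 1 rose, C1qb (1.46), or 2 adjusted over the list alone, and Cd68 was 234 ± 73.9 in Sham and 198 ± 19.8 in Gel (adjusted p = 0.731). Of 19 oxidative phosphorylation genes 3 fell, Uqcrb (-0.81), Atp5a1 (-0.72) and Sdhb (-0.65), or 6 adjusted over the list alone with 1 risen (list adjusted p = 1.4e-04, and adjusted p = 0.265 with an estimated correlation). These 3 calls were lost under 7, 8 and 11 of 23 alternatives, among them limma without trend and robust, quantile normalization, thinning, edgeR, DESeq2 and leaving out Sham specimen 1 or Gel specimen 1. Of 17 immediate-early and heat-shock genes Zfp36 (0.95), Dusp1 (0.97) and Fosb (1.17) rose and Dnajb1 (-0.78) fell, or 4 and 1 adjusted over the list alone, with no call for the list (adjusted p = 0.122). The 3 rises were lost under 5, 5 and 8 alternatives and the fall under 7, limma without trend and robust and DESeq2 among them. Of 20 lysosome and lipid-handling genes Apoe (1.10) and Cd9 (0.98) rose and Ctsd (-0.77) fell, or 2 and 2 adjusted over the list alone (list lower, adjusted p = 0.0260, and adjusted p = 0.290 with an estimated correlation). The Cd9 call was lost under 15 of 22 alternatives, including leaving out any 1 of the 6 specimens, and those of Apoe and Ctsd under 9 and 6 of 23, including leaving out Sham specimen 1. Of 18 unfolded protein response genes Manf (-0.72) and Pdia6 (-0.66) fell, or 5 adjusted over the list alone (adjusted p = 0.0238, and adjusted p = 0.505 with an estimated correlation). The Manf and Pdia6 calls were lost under 8 and 10 of 23 alternatives, among them quantile normalization, edgeR, DESeq2 and leaving out Sham specimen 1. All targets above background had a median log2 change of -0.147 (0.0085 under quantile normalization). Without their members of largest change the unfolded protein response and lysosome lists averaged -0.138 and -0.074. Their calls therefore cannot be told apart from this general shift. Of 19 proliferation genes 0 passed, also adjusted over the list alone, and the list was called higher (adjusted p = 0.0407, and adjusted p = 0.290 with an estimated correlation).

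In all, 122 targets were higher and 356 lower in Gel (478 of 19728), and 436 of them were above background. Of the 59 named genes past the threshold, 20 stayed past it under all alternatives: Mt1, C3, Prg4, Zbtb16, Lhx8, Gja5, Tagln, Tpm1, Cald1, Col12a1, Thbs2, Fn1, Fap, Mfap5, H2-Ab1, C1qtnf3, Ms4a4a, Ccn3, Itga11 and Mdk. Each of the others was lost under 1 or more. Cfb, Hba-a1, Lum and Plod2 were lost under 1, C1qb and Wnt5a under 2 and Mfap2 under 3. Of the 34 lists 11 were called at the preset correlation, 0 with an estimated one and 3 by fry, which tests a list by itself. When each list lost its member of largest change, 4 were called, contractile, matrix, fibroblast and oxidative phosphorylation. limma without trend and robust called 176 targets, DESeq2 152, the 24 areas as samples 771 and thinned counts 174, and quantile normalization gave 190 higher and 204 lower. Leaving out Sham specimen 1 gave 271 and leaving out Gel specimen 2 gave 752.

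**Figure D2:**
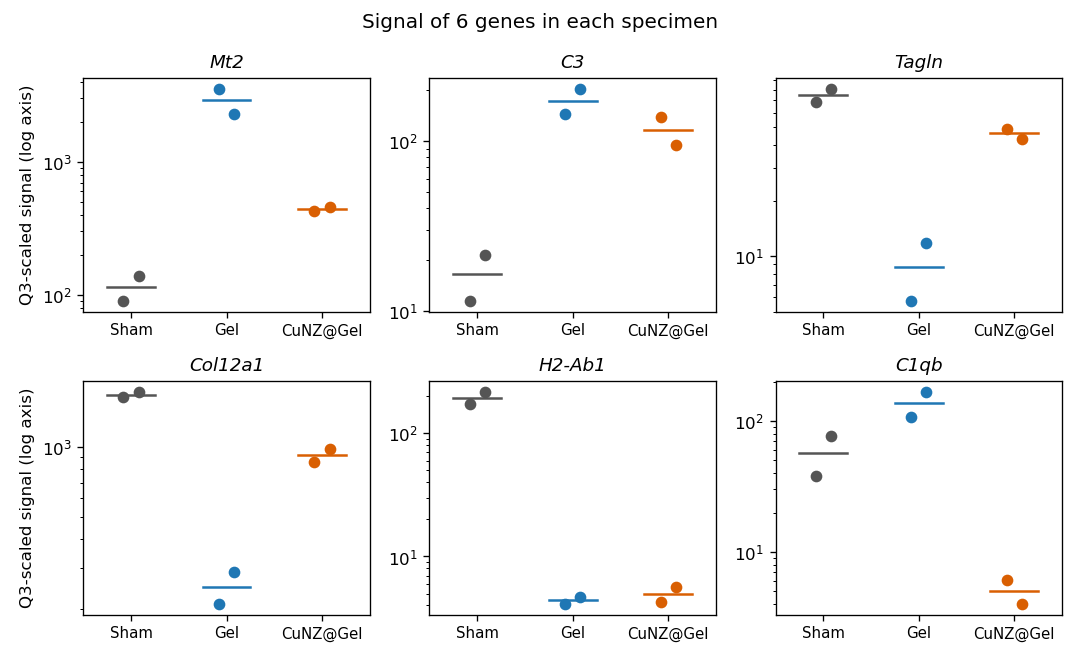
Signal (log axis) of Mt2, C3, Tagln, Col12a1, H2-Ab1 and C1qb in Sham, Gel and CuNZ@Gel, with a point per specimen (mean of 4 areas) and a line at the mean of the 2 specimens. Tagln was lowest in Gel (8.71) and stood at 46.3 in CuNZ@Gel and 74.7 in Sham, and C1qb was lowest in CuNZ@Gel (5.02).

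CuNZ@Gel against Sham asks what the loaded gel did. C3 was again higher (116 ± 30.8, log2 change 2.85, SE 0.20, adjusted p = 3.2e-22), and Mt2 stood at 444 ± 23.5 (1.99, adjusted p = 4.4e-14, lost under quantile normalization with adjusted p = 0.454), while Mt1, at 55.2 ± 3.50 against 41.7 ± 6.80, did not pass (0.35, adjusted p = 0.527). Tnn, which encodes the matrix protein tenascin-N, rose from 21.3 ± 8.71 to 140 ± 37.9 (2.76), and its relative Tnc rose by 1.55. Rpn2 (2.70), Rap1a (2.16), Ifi27l2a (2.11), Zic1 (1.75) and Ebi3 (1.57) also rose. Ifi27l2a (1.738), Zic1 (1.752) and Ebi3 (1.853) were called higher in Gel against Sham as well, and did not pass between the gels. H2-Ab1 (-5.03), Hba-a1 (-5.20), Hbb-b2 (-2.21), C1qb (-3.28), Col14a1 (-2.30), Ccn3 (-2.06), Mfap2 (-1.99) and 2310022A10Rik (-1.96) fell. H2-Ab1, Hba-a1, Hbb-b2 (-2.517), Col14a1 (-2.679), Ccn3 and Mfap2 were called lower in Gel against Sham as well. The calls of Col14a1 and Mfap2 were lost under 9 and 8 of 23 alternatives, among them quantile normalization and leaving out CuNZ@Gel specimen 2, and that of Hba-a1 under quantile normalization and the mean of linear values.

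Of the markers linked to alternatively activated macrophages, Arg1 fell from 193 ± 103 to 50.4 ± 6.19 (-1.84, SE 0.33, adjusted p = 0.0327) and Mrc1 from 54.4 ± 0.84 to 29.0 ± 2.78 (-0.81, adjusted p = 0.00953). They were 2 of 20 genes of that list, with 0 risen, also adjusted over the list alone, and the list was not called (adjusted p = 0.247). Each of the 2 calls was lost under 8 alternatives, that of Mrc1 on leaving out any Sham or CuNZ@Gel specimen. Arg1 was the list member of largest change between Gel and Sham as well. The mean log2 score of the list members above background was 5.94 in Sham, 5.52 in Gel and 5.38 in CuNZ@Gel. The fall of Arg1 is therefore not shown to be particular to the loaded gel. Of the pan-macrophage genes reported here C1qb fell and Lyz2 (0.71) rose, the latter lost under 9 of 23 alternatives, including leaving out Sham specimen 1 or either CuNZ@Gel specimen. The list of 20 was called lower (adjusted p = 0.0158, and adjusted p = 0.333 with an estimated correlation), but not without C1qb (adjusted p = 0.405). Of 23 antioxidant genes 3 fell, the ferritin genes Fth1 (-1.17) and Ftl1 (-0.81) and Gclm (-0.81), or 4 adjusted over the list alone (list adjusted p = 0.0158, and adjusted p = 0.333 with an estimated correlation). These 3 calls were lost under 6, 9 and 11 of 23 alternatives, among them limma without trend and robust, quantile normalization, edgeR and leaving out Sham specimen 1 or CuNZ@Gel specimen 1. Ftl1 was called lower in Gel against Sham as well (-0.82). Of the matrix list Eln (-1.06), Thbs2 (-0.88) and Col12a1 (-0.83) fell, 3 of 21, or 4 adjusted over the list alone, with adjusted p = 0.0158 and an adjusted p = 0.516 with an estimated correlation. The Eln call was lost under 4 of 23 alternatives and those of Thbs2 and Col12a1 under 10 each, and all 3 were lost by limma without trend and robust, by DESeq2 and on leaving out Sham specimen 1 or CuNZ@Gel specimen 1. Of 14 contractile genes Tnc rose and Tpm1 (-1.05) fell, or 1 and 2 adjusted over the list alone, with no call for the list (adjusted p = 0.291). Without Tnc the list was called lower at the preset correlation (adjusted p = 0.0326). Ccn2 (1.26), a matricellular growth factor gene, rose, a call lost under 5 alternatives, leaving out Sham specimen 1 or CuNZ@Gel specimen 2 among them. Of 20 lysosome and lipid-handling genes Ctsl (-1.42) and Ctsd (-0.87) fell and Apoe (0.81) rose, also adjusted over the list alone (list lower, adjusted p = 0.00224, and adjusted p = 0.333 with an estimated correlation). The Apoe call was lost under 18 of 23 alternatives and that of Ctsd under 8, both including leaving out Sham specimen 1 or either CuNZ@Gel specimen, and that of Ctsl under 3. Of 18 fibroblast genes 2 fell, or 2 with 1 risen adjusted over the list alone (list lower, adjusted p = 0.00224, and adjusted p = 0.516 with an estimated correlation). Of 19 oxidative phosphorylation genes Atp5a1 (-0.77) fell, or 7 with 1 risen adjusted over the list alone (list lower, adjusted p = 4.8e-05, and adjusted p = 0.333 with an estimated correlation), and the Atp5a1 call was lost under 8 of 23 alternatives, including leaving out Sham specimen 1 or either CuNZ@Gel specimen. Of 13 hypoxia genes Ddit4 (0.99) rose, or 2 adjusted over the list alone (adjusted p = 0.0159, and adjusted p = 0.516 with an estimated correlation), and the Ddit4 call was lost under 6, including leaving out CuNZ@Gel specimen 2.

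In all, 64 targets were higher and 195 lower (259), 241 of them above background. All targets above background had a median log2 change of -0.155 (-0.020 under quantile normalization). The antioxidant list averaged -0.132 without Fth1, so its call cannot be told apart from this general shift. Of the 42 named genes past the threshold, 10 stayed past it under all alternatives: C3, Tnn, Rpn2, Ifi27l2a, Ebi3, H2-Ab1, Hbb-b2, C1qb, Ccn3 and 2310022A10Rik. Each of the others was lost under 1 or more. Rap1a and Zic1 were lost under 1, and Tnc and Tpm1 under 3. Of the 34 lists 8 were called at the preset correlation, 0 with an estimated one and 1 by fry. When each list lost its member of largest change, 4 were called, all lower: lysosome (adjusted p = 0.0438), fibroblast (0.0326), contractile (0.0326) and oxidative phosphorylation (0.00106). limma without trend and robust called 44 targets, DESeq2 59, edgeR 165, thinned counts 47, median scaling 146, the 24 areas as samples 517, a fit without Gel 461, and quantile normalization 159 (79 higher, 80 lower). Leaving out Sham specimen 1 gave 72, CuNZ@Gel specimen 1 89 and CuNZ@Gel specimen 2 93, and leaving out either Gel specimen gave 458. Between the comparisons against Sham, 19 targets were higher in both gels, 103 were lower in both and 2 were called in opposite directions. Simulations of unchanged groups that shared simulated Sham specimens gave 0.45 higher and 0.30 lower in both, and independent lists 0.396 and 3.52. Targets varied independently in the simulations, which therefore leave out shifts of the Sham specimens common to many targets. The log2 changes had a covariance of 0.0801, against 0.0380 simulated, a difference of 0.0421. Sham held 2 specimens, too few to split, and part of the excess may come from the shared controls.

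CuNZ@Gel against Gel compares the gels with and without the nanozyme, as their names give it. Of its 186 calls, 125 were also called between Gel and Sham in the opposite direction. Both comparisons use the same 2 Gel specimens, so these calls are not separate evidence of an effect of the nanozyme. Tagln, Col12a1 and Thbs2 were higher in CuNZ@Gel: Tagln stood at 46.3 ± 4.06 against 8.71 ± 4.26 (log2 change 2.39, SE 0.21, adjusted p = 6.5e-17), Col12a1 at 923 ± 82.5 against 248 ± 55.5 (2.19), and Thbs2 at 395 ± 18.5 against 105 ± 23.6 (2.07). The largest rise was Tnn, from 3.70 ± 0.27 to 140 ± 37.9 (4.94, adjusted p = 1.2e-34). C1qtnf3 (2.87), Ms4a4a (2.83), Rpn2 (2.68) and Rasl11b (2.16) rose too. The metallothionein genes were lower, Mt2 by -2.68 (adjusted p = 5.1e-21, lost under quantile normalization with adjusted p = 0.343) and Mt1 by -2.48 (lost there with adjusted p = 0.0530), as were C1qb (-4.74), Prg4 (-2.50, lost there with adjusted p = 0.0847), Gja5 (-2.04), 2310022A10Rik (-1.83), the transferrin gene Trf (-1.69) and Ndufs3 (-1.65).

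Of 14 contractile genes 4 rose and 0 fell, also adjusted over the list alone: Tagln, Tnc (2.07), Tpm1 (1.18) and Cald1 (1.07), with adjusted p = 1.1e-29 and an adjusted p = 0.0627 with an estimated correlation. Of 21 matrix genes 6 rose and 1 fell (9 and 2 adjusted over the list alone), among them Plod2 (1.69) and Fn1 (1.38), with adjusted p = 4.9e-18 and an adjusted p = 0.112 with an estimated correlation. Of 19 wound growth factors Wnt5a (1.65), Ccn2 (1.73) and Ccn1 (1.09) rose, or 4 with 1 fallen adjusted over the list alone (list adjusted p = 7.7e-06, and adjusted p = 0.159 with an estimated correlation). The Ccn1 call was lost under 6 of 22 alternatives, including leaving out Gel specimen 2 or either CuNZ@Gel specimen. Of 18 fibroblast genes Mfap5 (1.48) and Lox (0.82) rose, or 2 with 1 fallen adjusted over the list alone (adjusted p = 1.1e-05, and adjusted p = 0.443 with an estimated correlation). The Lox call was lost under 8 of 23 alternatives, including edgeR, DESeq2 and leaving out either CuNZ@Gel specimen. The adipocyte list (0 of 14 past the threshold, adjusted p = 0.0455, and adjusted p = 0.738 with an estimated correlation) and the proliferation list (0 of 19, adjusted p = 0.0455, and adjusted p = 0.426 with an estimated correlation) were called lower, with 0 also adjusted over the list alone. Of 20 endothelial genes Nos3 (-0.95) fell, also adjusted over the list alone (list lower, adjusted p = 0.0455, and adjusted p = 0.738 with an estimated correlation). The Nos3 call was lost under 7 of 23 alternatives, including edgeR, DESeq2 and leaving out Gel specimen 2 or CuNZ@Gel specimen 1. Of 25 copper and metal genes Mt1 and Mt2 fell, also adjusted over the list alone (adjusted p = 0.00137, and adjusted p = 0.426 with an estimated correlation). Of 20 alternatively activated macrophage genes Mrc1 fell by 1.14 on the log2 scale (adjusted p = 1.5e-05), also adjusted over the list alone, and the list was not called (adjusted p = 0.685). Of 20 lysosome and lipid-handling genes the cathepsin gene Ctsl fell by 1.49, or 2 fell adjusted over the list alone, and the list was not called (adjusted p = 0.790). The Ctsl call was lost under quantile normalization, with the 24 areas as samples and without the shallowest area. C1qb was the only one of 20 pan-macrophage genes past the threshold over all targets, or 2 fell and 1 rose adjusted over the list alone (list lower, adjusted p = 0.00183, and adjusted p = 0.25 with an estimated correlation). Without C1qb the list was not called (adjusted p = 0.47). C1qa (-0.11, adjusted p = 0.995) and C1qc (-0.13, adjusted p = 0.997), its partners in the C1q complex, did not pass; C1qa was named after its values were seen.

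In all, 123 targets were higher and 63 lower (186), 180 of them above background. Of the 37 named genes past the threshold, 13 stayed past it under all alternatives: Tagln, Col12a1, Thbs2, Tnn, C1qtnf3, Ms4a4a, Rpn2, Rasl11b, Ccn2, Mfap5, C1qb, Gja5 and Trf. Each of the others was lost under 1 or more. Fn1, Mrc1, Wnt5a, Ndufs3 and 2310022A10Rik were lost under 1, Plod2 and Tpm1 under 2, and Cald1 and Tnc under 4. Of the 34 lists 9 were called at the preset correlation, 0 with an estimated one and 0 by fry. When each list lost its member of largest change, 4 were called, contractile, matrix, fibroblast and wound growth factors. limma without trend and robust called 75, DESeq2 55 and thinned counts 80, and leaving out Gel specimen 2 gave 293, CuNZ@Gel specimen 1 106 and CuNZ@Gel specimen 2 95.

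Of the genes given in every treatment comparison, Nos2, Il1b, Tnf, Il6, Cd163, Il10 and Hmox1 were above background in 0 of 24 areas, and Cd86 in 1, so no difference in their levels could be read. The histone modifier genes Kdm6b (39.9 ± 0.66 in Sham, 31.7 ± 13.4 in Gel, 41.7 ± 8.91 in CuNZ@Gel) and Ezh2 (12 ± 1.51, 11.5 ± 5.64 and 9.33 ± 1.83) passed in no treatment comparison. The Ezh2 means lay under the median background of 14.3, so little can be read from its lack of a call. Of 31 chromatin modifiers Uhrf1 (1.09) rose and Kdm1a (-0.73) fell between Gel and Sham, also adjusted over the list alone, and 0 passed in the other comparisons of treatments. The Kdm1a call was lost under 9 of 23 alternatives, including edgeR, DESeq2 and leaving out either Sham specimen or Gel specimen 1, and that of Uhrf1 under thinning and DESeq2. Sod1 (151 ± 6.85, 108 ± 13.3 and 99.4 ± 9.53) and Vegfa (9.32 ± 1.08, 11.1 ± 3.91 and 12 ± 1.57) passed in none. The Vegfa means, too, lay under the median background, with the same limit.

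Segment 2 was compared with Segment 1 within the 6 specimens. Aplnr, Nos3, Mcam, Sox18 and Rgs5 were among the genes with the largest falls in Segment 2: Aplnr stood at 148 in Segment 1 and 68.1 in Segment 2 (log2 change -1.15, SE 0.12, adjusted p = 2.3e-08), Nos3 at 65.9 and 30.9 (-1.12), Mcam at 173 and 85.3 (-1.07), Sox18 at 157 and 78.2 (-1.08), and the pericyte gene Rgs5 at 104 and 55.5. Itga6 (-1.12), Efna1 (-1.02) and Rapgef3 (-1.02) fell as well. Of 20 endothelial genes Nos3 and Plvap (-0.97) fell, or 6 with 2 risen adjusted over the list alone (list adjusted p = 0.0343, and adjusted p = 0.361 with an estimated correlation). Of 21 matrix genes 5 fell, among them Col6a1 (-0.46) and the basement membrane gene Col4a1 (1212 and 622), or 9 adjusted over the list alone (list adjusted p = 3.0e-09, and adjusted p = 0.239 with an estimated correlation). Of 18 fibroblast genes Cd34 (-0.95), Thy1 (-0.63) and Col1a1 (-0.43) fell, or 4 adjusted over the list alone (list adjusted p = 2.8e-07, and adjusted p = 0.239 with an estimated correlation). Of 20 pan-macrophage genes Csf1r (-0.49), Lgmn (-0.32) and Lyz2 (-0.33) fell, or 6 with 1 risen adjusted over the list alone (list adjusted p = 0.0108, and adjusted p = 0.459 with an estimated correlation). Lists with 0 members past the threshold were called too: ribosomal protein lower (19 genes, adjusted p = 0.0108, and adjusted p = 0.563 with an estimated correlation), and higher neutrophil (19 genes, 1 above background, adjusted p = 0.0126, and adjusted p = 0.239 with an estimated correlation) and mast cell (10 genes, 0 above background, adjusted p = 0.0464, and adjusted p = 0.361 with an estimated correlation). Of 19 proteases and inhibitors 3 fell, or 5 with 2 risen adjusted over the list alone (list adjusted p = 0.0464, and adjusted p = 0.361 with an estimated correlation), and of 17 immediate-early and heat-shock genes 4 fell, also adjusted over the list alone (list adjusted p = 0.0343, and adjusted p = 0.459 with an estimated correlation). The median log2 change of all targets above background was -0.20. The contractile list was not called (adjusted p = 0.744). Without their members of largest change the endothelial (adjusted p = 0.228), immediate-early (0.144) and mast cell (0.147) lists were not called.

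In all, 314 targets were lower and 67 higher in Segment 2. Of the lower ones 305 were above background, and of the higher ones 0, among them Ins2 (2.25 and 6.41), Tomm70a (1.71 and 4.55) and Pkd2l1 (3.21 and 7.97). limma without trend and robust called 0 (2458 at an unadjusted p under 0.05), against 340 by edgeR (54 higher) and 142, all lower, by DESeq2. Thinned counts gave 48, all lower, quantile normalization 130 (30 higher), no specimen block 167 (32 higher) and median scaling 1336 (66 higher). Of the 44 named genes past the threshold, 0 stayed past it under all alternatives. Leaving out Gel specimen 1 gave 239, Gel specimen 2 198 and CuNZ@Gel specimen 1 241.

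The treatments were also compared in each segment. Gel against Sham gave 364 targets in Segment 1 and 308 in Segment 2, CuNZ@Gel against Sham 192 and 116, and CuNZ@Gel against Gel 150 and 119. The targets called in both segments, 167, 53 and 63 in that order, all had the same direction in both. Of those called in either segment, 490 of 505, 243 of 255 and 200 of 206 did. The segments come from the same specimens, so this is not independent replication. The interaction test named 10 genes whose treatment effect differed between segments: Acta2 (adjusted p = 0.00135), Vim, Igfbp4, Col4a1, Col15a1, Actb, Tmsb10, Sox18, Prrx1 and Actg1. Acta2 averaged 492 in Segment 1 and 671 in Segment 2 of Sham, 85.5 and 59.9 in Gel, and 433 and 349 in CuNZ@Gel. Taken by pairs of treatments, the interaction passed for 12 genes in Gel against Sham, 4 in CuNZ@Gel against Sham and 0 in CuNZ@Gel against Gel. For each of the 10 genes its value was negative in both gels against Sham. No segment effect that differed between the gels was found, by a test that recovered few small simulated changes. All 10 are given because they passed, not by the rule for named genes. Leaving out Sham specimen 1 gave 0 genes by limma (792 at an unadjusted p under 0.05), leaving out Sham specimen 2 gave 1, which was not among the 10, and leaving out Gel specimen 1 gave 1, which was. Leaving out Gel specimen 2 gave 20 (7 of the 10 among them), CuNZ@Gel specimen 1 17 (9) and CuNZ@Gel specimen 2 36 (10). Quantile normalization called 13, of which 2 were among the 10, the mean of linear values 7 (4), thinned counts 17 (7), edgeR 4 (2), a pseudocount of 5 3 (2) and median scaling 2 (1).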

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

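The tests of the on/off targets and of the contractile genes were chosen after the results were seen, and those of the segments before. An area was singled out when it lay far from the other 7 areas of its treatment. This happened 17 times in 135 groups of areas examined. The rule gives about 1 in 20 for independent normal values. The areas differ in depth and share specimens, and the groups reuse the same areas, so that rate need not hold here. The CuNZ@Gel specimen 1 region 1 Segment 2 area, the shallowest of all, accounted for 8 of the 17. It had 46.9% of targets at 1 count and low mean log2 scores for pro-inflammatory macrophage genes (4.36), wound growth factors (4.72), chromatin modifiers (4.40), glycolysis (5.03), oxidative phosphorylation (5.13) and proliferation (3.11), and low Col1a1 (150). Without it the treatment comparisons called 501, 201 and 198 targets. The Gel specimen 1 region 2 Segment 2 area had the highest negative probe (5.42), and without it 513, 287 and 220 were called. Sham specimen 2 region 2 had high Col1a1 (829) and Col3a1 (25510) in Segment 1 and a low protease score (5.99) and high Cd86 (10.2) in Segment 2. CuNZ@Gel specimen 2 region 1 Segment 2 had high Cd86 (46.3) and Cd163 (5.45), Gel specimen 2 region 2 Segment 2 a low copper and metal score (5.32), and Sham specimen 1 region 1 Segment 1 a low ribosomal score (7.25). The Cd163 value of 5.45 and the Sham Cd86 value of 10.2 lay below the background of their areas (21.6 and 14.3), so neither difference can be read.

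The interaction test singled out 10 genes, with adjusted p = 0.00135 for Acta2, 0.00727 for Vim, 0.00741 for Igfbp4 and Col4a1, 0.0295 for Col15a1 and Actb, and 0.0480 for Tmsb10, Sox18, Prrx1 and Actg1.

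Of 14 contractile genes 3 fell in Gel (list adjusted p = 6.7e-23, and adjusted p = 0.0920 with an estimated correlation), and the median log2 change was -2.23 over the 7 above background, of which Acta2, Tpm2, Postn and Tnc did not pass. Scaling is argued against, since the median was -1.93 or lower under each other scaling and count test, and so is a single region or specimen, since each part gave -1.79 or lower. Fewer fibroblasts in the Gel areas may contribute, and the values do not settle it. The 11 genes above background of the fibroblast list fixed beforehand had a median of -1.23. A part of these, 4 general fibroblast genes chosen after the data were seen, had -0.32, from -1.23 (Thy1) to 0.28 (Cd34). A smaller share of fibroblasts cannot be told apart from a change within fibroblasts, because the answer depends on the fibroblast genes taken and no cell counts were used here. The adipocyte list was also called higher in Gel at the preset correlation (adjusted p = 0.0259, and adjusted p = 0.449 with an estimated correlation), though not without Fabp4 (adjusted p = 0.224). An effect of the gel itself on contractile cells stays open and was not tested.

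H2-Ab1 was above background in 8, 0 and 0 of 8 areas of Sham, Gel and CuNZ@Gel, C1qb in 8, 8 and 0 and Rpn2 in 0, 1 and 8, and H2-Ab1 alone stood over 2 times background in all areas of a treatment and at or below background in all others. A joint change with genes of the same pathway or complex is argued against, since genes such as Cd74, H2-Eb1, C1qa and Ddost had a median change of 0.115 in the direction of the switched gene. A sequence difference at the probe site may explain them. If each specimen came from an unrelated animal, on/off targets would also appear within treatments. The mean was 0 there, against 6.17 between specimens of different treatments, a count that also holds genes the treatments changed. Pairs of different treatments ran from 2 to 17, with the highest, 17 and 14, between Gel specimen 1 and the Sham specimens. A difference shared by the specimens of a treatment cannot be told apart from an effect of the treatment on these genes alone, because both follow the treatment and the files hold no genotypes.

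The 67 targets higher in Segment 2 may come from its lower depth: after every area was thinned to the lowest total 0 were higher. Thinning also cut the lower targets from 314 to 48, so it cannot tell a depth effect from a general loss of calls. edgeR on the recovered counts still called 54 higher. For the segment comparison as a whole chance is argued against, though 32 assignments of the segments within specimens are too few to exclude it. The real one gave 381 targets, and the highest of the others gave 36. Segment 2 was the shallower in 11 of 12 regions, so this does not separate the segments from their depth. limma without trend and robust called 0 targets.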

How the results depend on the processing

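The alternatives using the recovered counts, the receptor background, thinning, and the omission of single areas and of list members were chosen after seeing the data. So were those for the numbers of targets called within 1 segment, while the list tests within 1 segment were planned. Of the named genes past the threshold, 20 of 59 stayed past it under all alternatives for Gel against Sham, 10 of 42 for CuNZ@Gel against Sham, 13 of 37 for CuNZ@Gel against Gel and 0 of 44 between segments, and 0 reversed. Where an omission leaves 1 specimen in a treatment, that specimen is assumed to vary like the others. The counts between Gel and Sham (478), CuNZ@Gel and Sham (259), CuNZ@Gel and Gel (186), the segments (381) and of the interaction (10) moved as follows, and the cause was not tested except where fewer targets, counts or specimens entered. limma without trend and robust gave 176, 44, 75 and 0 (2458 at an unadjusted p under 0.05) in the first 4. Thinning to the lowest total gave 174, 47, 80, 48 and 17. DESeq2 gave 152, 59, 55 and 142, and edgeR 165 for CuNZ@Gel against Sham and 4 for the interaction. The 24 areas as samples gave 771 for Gel and 517 for CuNZ@Gel against Sham, and the latter was 461 with only the 2 treatments compared. Quantile normalization gave 159 for CuNZ@Gel against Sham and 130 between segments, and median scaling 146, 1336 and, for the interaction, 2. Median scaling moved the median of all targets between segments to -0.13. The interaction count was 3 with a pseudocount of 5 and 1 with the receptor background as filter. Without a replicate block the segment count was 167.

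Leaving out each specimen gave 271 to 752, 72 to 458, 95 to 293, 198 to 404 and 0 to 36 in that order. Within Segment 1 it gave 191 to 600 for Gel against Sham, 52 to 359 for CuNZ@Gel against Sham and 66 to 239 for CuNZ@Gel against Gel, and within Segment 2 142 to 314, 32 to 159 and 72 to 151. CuNZ@Gel against Sham in Segment 2 gave 72 with the receptor background as filter and 59 by edgeR. With an estimated correlation camera called 0 lists in each of the 4 comparisons, against 11, 8, 9 and 9 at the preset one, and fry called 3, 1, 0 and 0. When each list lost its member of largest change, 4, 4, 4 and 6 were called. This can also strengthen a list: without Tnc the contractile list between CuNZ@Gel and Sham moved from adjusted p = 0.291 to 0.0326. In Segment 2 alone 4 lists were called for CuNZ@Gel against Sham. With the specimen number as a replicate block the treatment counts were 500, 257 and 201. Deviations of specimens of the same number correlated at -0.016, -0.018 and 0.074 over all targets, so the numbers were not taken to pair specimens. Depth limits what Segment 2 can show, since a median of 28.5% of its targets stood at 1 count.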

Other observations

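The test without Hba-a1 and the values of single genes in this part were chosen after the results were seen. Of the 5 measured genes of the erythroid list Hba-a1 alone fell in Gel and in CuNZ@Gel against Sham, also adjusted over the list alone, and it was the 1 member above background. The list was called lower in both (adjusted p = 9.0e-04 and 6.1e-06, and adjusted p = 0.265 and 0.333 with an estimated correlation), and in neither without Hba-a1 (adjusted p = 0.999 and 0.577). Hbb-b2, which is not on the list, was called lower in both (-2.517 and -2.205). Hba-a1 averaged 1086 ± 253 in Sham, 31.9 ± 3.48 in Gel and 41.5 ± 31.3 in CuNZ@Gel (SD, n = 2), and Hbb-b2 28.7 ± 7.44, 4.50 ± 0.88 and 5.52 ± 1.73. Trf averaged 65.1 ± 19.2, 232 ± 44.1 and 72.1 ± 5.94 in that order. The Gel specimens lay apart in some contractile genes, with Postn at 4.85 and 6.58 and Tpm2 at 4.26 and 5.70 on the log2 scale, where the Sham specimens stood at 6.83 and 7.60, and at 7.82 and 7.66.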
